A study of Rattus norvegicus with 10 samples.

How the data were processed

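RNA from rat lung was labelled with Cy3 and hybridised to single-colour Agilent arrays, 1 array per sample, per the labels' protocols. The labels gave 5 samples as LPS and 5 as control. The labels' replicate numbers name the samples, and no number occurs in both groups. The scanner files hold spot intensity values on a linear scale that the authors deposited as they left Agilent Feature Extraction 11.0.1.1, which subtracted the background and detrended the spots, per the file headers. The deposited intensity values were not normalized between arrays. The authors also deposited a table of log2 values, 1 per probe and sample. Its tool is not given in the sources used here. Its 10 columns share their median of 6.18 and their quartiles, as the columns of a quantile-normalized table do, and its values correlated with log2 scanner signal at r = 0.994 to 0.996 across probes. Its scale and direction follow from that match, and what else was done to it stays unknown.

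The main values were log2 of the processed signal minus each array's 75th percentile of it. Control spots and spots marked as outliers were left out, and spots of 1 probe were averaged. Of 41800 noncontrol spots and 38804 probes, 126 probes were left out for outlier spots on an array. A further 2658 probes that were not well above background on at least 5 of the 10 arrays were left out as dim. The remaining 36020 probes were tested with limma 3.58.1 in R 4.3.3, 2-sided, with lmFit and eBayes on the groups alone, and Benjamini-Hochberg adjustment over all tested probes. The threshold was an adjusted p of 0.05, and a second count took changes of at least 2-fold. Direction is LPS minus control.

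The probe identifiers are codes of a custom design, and gene names were found only through the accessions of 50 Agilent catalogue probes. Of these, 30 matched a rat gene in the RefSeq gene table of assembly GRCr8, used for names only, and 29 of the matched genes were tested. No gene had several named probes. The planned tests of 36 gene lists needed at least 5 named members, and no list had more than 1, so they were not run. The planned comparison of long noncoding RNA genes with their neighbours was not run, since those probes could not be matched to genes. Co-expression of long noncoding and messenger RNA was not tested, as 5 arrays per group are too few for a correlation within a group.

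The class of a probe came from its identifier: 3324 tested probes carry the letters LNC, 700 carry the name and strand of an ultraconserved region, 48 are Agilent catalogue probes and 31948 are other custom probes, whose class is not given in the sources used here. The rule for named genes was set before the data were examined. It took up to 6 rises and 6 falls with a symbol, past the threshold, with no overlap between the groups. Each had to be well above background on every array of the higher group and on some array of the lower group. The rule gave Fgf2, Cdh2, Ndfip2, Cyp2e1, Map2 and Med16. It also took members of described lists, Tnf, Il1b, Il6 and Il10, and long noncoding RNA probes, of which 2 that rose and 2 that fell are printed. The other 4 called genes, Nlrp3, Ldha, Nat1, Pld1, Ptk2b and Pdk3 were named after their values were seen, as were the largest changes at unnamed probes.

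Where an array was not well above background, its floor was the lowest signal among probes well above background on that array. A fold change taken from a floor is no strict bound, since a dim probe may truly lie above it. Slides were read from the scan stamps in the file headers. Slide was used as a fixed block, which leaves only slide 3 to inform the comparison, and as a random block with duplicateCorrelation and statmod 1.5.0. Other alternatives were normexp with an offset of 50, quantile normalization, median centring, the authors' log2 table, other filters, eBayes with trend and robust settings, array weights and leaving out each array. The planned normexp correction of mean signals was run on median spot and background signals, which the files hold. Spread between rats was tested by assigning the 10 group-centred arrays to sets of 5 in every way, and such centred arrays are only approximately exchangeable. Counts of probes were also set against other splits of the arrays.

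The number of arrays limits the precision. On 159 probes with 10 to 20 spots per array, the median SD between spots was 0.11 on the log2 scale, against 0.17 between LPS arrays, 0.25 between controls and 0.16 between the slide 2 controls alone. The limma step was tested on simulated data for the LPS comparison with 36020 probes. The simulated arrays held no slide difference and no array that lay apart from its group, as control replicate 20 did. Their spread came from the LPS arrays and the slide 2 controls. In a single draw 67, 67 and 66 probes were changed, by 0.5, 1 and 2 on the log2 scale. On the measured arrays far more probes were called, so the rates may not hold for them. The fit recovered 38.8% of probes changed by 0.5 on the log2 scale, 79.1% of those changed by 1 and 95.5% of those changed by 2. In that draw 16 of its calls were false, 10.1%, above the nominal 5%, which a single draw does not establish as a rate. With slide as a block it recovered 0%, 19.4% and 78.8%, with 0 false calls.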

Results

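RNA of lung tissue from male Wistar rats aged 8 weeks was measured on 10 single-colour Agilent microarrays, 5 from rats with septic shock induced by lipopolysaccharide (LPS) and 5 from control rats. LPS is a component of the outer membrane of Gram-negative bacteria that sets off a strong innate immune response. The dose, route and time of LPS are not given in the sources used here. The custom array carried 38804 probes other than controls, and 36020 of them were tested. Between 90.1% and 93.8% of the spots on each array were well above background. The 75th percentile of the spot signal lay between 264.9 and 474 per array, and no spot was saturated. The labels number the samples but do not say that each came from a separate animal, so p-values measure the spread between these samples.

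The arrays lay on 3 slides. Slide 2 held 4 of the controls and no LPS array, slide 1 held 2 LPS arrays, and slide 3 held 3 LPS arrays with control replicate 20. A value within a slide therefore compares 3 LPS arrays with 1 control array, which is assumed to vary like the others. That assumption is in doubt. The log2 differences of control replicate 20 from the mean of the other controls had an SD of 0.74 over probes. The same measure, each array against the rest of its group, was 0.23 to 0.38 for all others. The p-values with slide as a block may therefore be too small. The slide 2 controls correlated with one another at r = 0.992 to 0.994 across probes, and the LPS arrays at 0.986 to 0.996. Control replicate 20 correlated with the LPS arrays at 0.971 to 0.983 and with the other controls at 0.964 to 0.971. These correlations run across probes, which are not independent replicates.

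**Figure D1:**
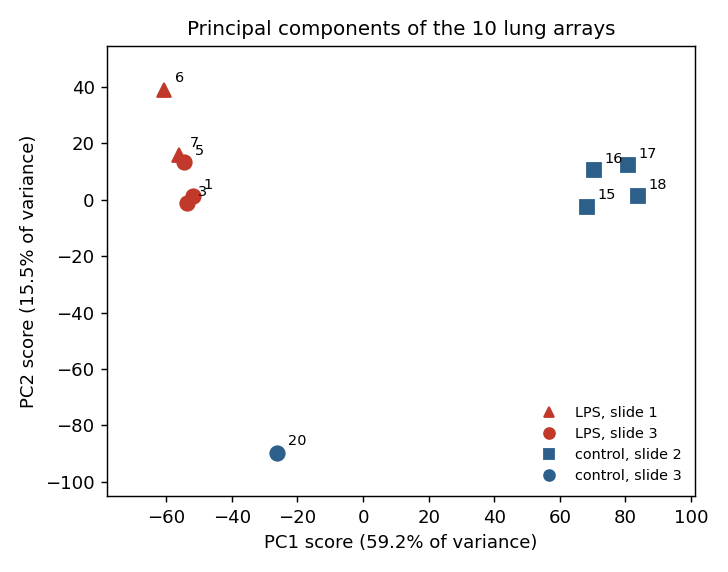
Scores of the 10 arrays on the first and second principal components of log2 signal over 36020 probes (59.2% and 15.5% of the variance), with each replicate number beside its point, colours for groups and shapes for slides. The slide 2 controls lie between 68.2 and 83.9 on the first component, the LPS arrays between -60.6 and -51.9, and control replicate 20 at -26.1.

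The first comparison asked which transcripts differed in the lung between rats given LPS and controls. Fgf2, a growth factor for fibroblasts and endothelial cells, rose 2.65-fold in LPS lungs, from a log2 signal of -2.72 ± 0.21 (SD, n = 5) in controls to -1.31 ± 0.54 (SD, n = 5), relative to each array's 75th percentile. Cdh2, which encodes the adhesion protein N-cadherin, rose 1.80-fold, from 3.20 ± 0.25 (SD, n = 5) to 4.05 ± 0.30 (SD, n = 5). Cyp2e1, which encodes an ethanol-oxidising cytochrome enzyme, fell from -1.24 ± 0.30 (SD, n = 5) to -2.28 ± 0.54 (SD, n = 5), and its control signal was 2.06-fold its LPS signal. The rule that chose these 3 genes required all 5 LPS arrays to lie beyond all 5 controls. That separation is therefore no added support. For Cyp2e1 it was narrow, with LPS replicate 5 at -1.54 and control replicate 20 at -1.50. The adjusted p of limma's moderated test was 0.0014 for Fgf2, 0.00398 for Cdh2 and 0.00842 for Cyp2e1. Fgf2 was 1.31 higher on the log2 scale within slide 3 and Cdh2 1.11 higher, with adjusted p = 0.0273 and 0.027 when slide was a block in limma. Cyp2e1 had a difference of -0.62 within slide 3, with a limma adjusted p of 0.395, so its call was lost.

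Of the 29 genes with a symbol that were tested, 10 passed the threshold, 5 higher and 5 lower in LPS lungs. When slide was a block 9 passed, all 9 higher, and 4 of them were among the 10. Without control replicate 20, 16 passed, 6 higher and 10 lower. Ndfip2, an adaptor of ubiquitin ligases, rose by a log2 fold change of 0.37 ± 0.13 (SE), and Napepld, an enzyme that makes N-acylethanolamines, rose by 0.60 ± 0.17 (SE). Their limma adjusted p was 0.0469 and 0.0184. Slc28a2, a nucleoside transporter, rose by 0.55 ± 0.16 (SE), with a limma adjusted p of 0.024. Control replicate 20, the only control on slide 3, was the lowest control for Ndfip2 and Napepld. When that array was left out, Ndfip2 rose by 0.27 and Napepld by 0.49. Within slide 3 Ndfip2 was 0.68 higher and Napepld 1.09 higher, and both stayed past the threshold with slide as a block (limma adjusted p = 0.0256 and 0.027). In a limma fit of slide 3 alone the adjusted p of Ndfip2 was 0.109, and with trend and robust eBayes it was 0.0514, so its call was lost in both. Slc28a2 was 0.39 higher within slide 3, with an adjusted p of 0.435 under the limma slide block. Leaving out any 1 of LPS replicates 3, 5, 6 and 7 or control replicates 15, 16, 17 and 18 ended the call of Ndfip2, with limma adjusted p values between 0.0511 and 0.1. Leaving out LPS replicate 5 or 7 or control replicate 17 or 18 did so for Slc28a2, with limma adjusted p values between 0.0585 and 0.0629.

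Map2, which encodes a microtubule-associated protein of neurons, fell by 0.67 on the log2 scale, and Med16, a subunit of the Mediator complex, fell by 0.60. Their limma adjusted p was 0.00652 and 0.00552. Dlg4, a scaffold protein of synapses, fell by 0.59, and Gdnf, a neurotrophic factor, fell by 0.78, at limma adjusted p values of 0.0339 and 0.0194. Map2, Dlg4 and Gdnf were dim. Signals before scaling were 16.8 in LPS and 19.6 in control arrays for Map2, 14.0 and 15.5 for Dlg4 and 5.79 and 7.29 for Gdnf. The 75th percentile used for scaling was 265 to 333 on slide 2 and 366 to 474 on the other slides. Part of each log2 fall therefore rests on the scaling. The LPS and control values of Dlg4, Gdnf, Napepld and Slc28a2 overlapped. None of the 4 falls held within slide 3, where the difference was -0.23 for Map2, -0.21 for Med16, 0.026 for Dlg4 and 0.15 for Gdnf. In the limma fit with slide as a block, their adjusted p was 0.525, 0.434, 0.949 and 0.74. The Dlg4 signal of control replicate 20 was -5.14, against a mean of -4.24 in the slide 2 controls and -5.01 in the LPS arrays. Dlg4 was lost without any 1 of LPS replicates 1, 3, 5 and 7 or control replicates 15, 16, 17 and 18, at limma adjusted p values between 0.0569 and 0.0868. Gdnf was lost without control replicate 17 or 18, at limma adjusted p values of 0.0507 and 0.0503, and in the authors' deposited table, at -0.45 and 0.0524. It was not well above background on LPS replicate 3 and control replicate 20, so its sign within slide 3 is not readable.

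**Figure D2:**
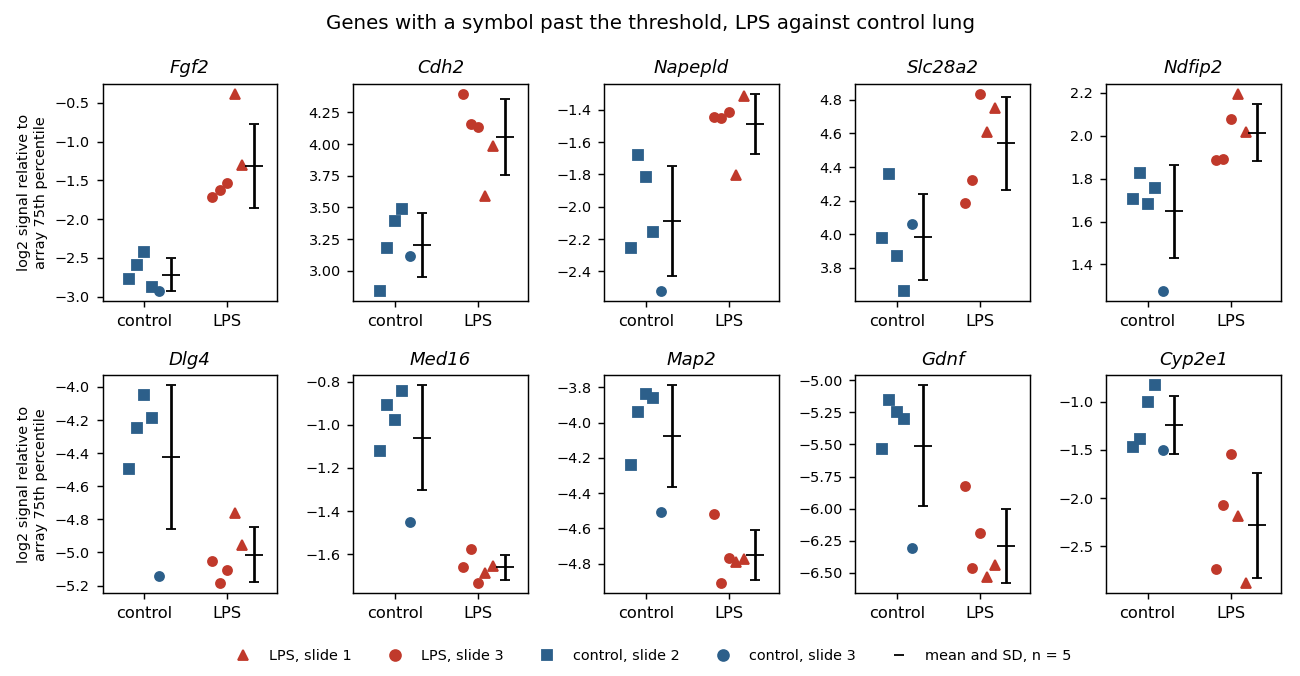
Log2 signal relative to the array's 75th percentile on each array, for the 10 genes with a symbol that passed the threshold, with colours for groups, shapes for slides and bars for the mean and SD of 5 arrays. Fgf2 in control replicate 20 lies at -2.93, below every LPS array, whereas Gdnf in that array lies at -6.31, not well above background, with an LPS mean of -6.29.

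The other 19 genes with a symbol did not pass the threshold, with log2 fold changes between -0.40 and 0.35 and limma adjusted p values from 0.0788 upward. Among them were Nlrp3, the sensor of an inflammasome, and Ldha, a subunit of lactate dehydrogenase. These were the only members of the 36 gene lists fixed beforehand that had a named probe, so no list was tested. Nlrp3 differed by -0.27 ± 0.33 (SE), with a limma adjusted p of 0.538. Control replicate 20 was the lowest control, at -6.37, and the only array of the 10 on which Nlrp3 was not well above background. Within slide 3 the mean of the LPS arrays was 1.69-fold above the floor of control replicate 20. The measured log2 difference was 1.13, with a limma adjusted p of 0.0305 with slide as a block. Without control replicate 20 the log2 difference was -0.63, with a limma adjusted p of 0.00533. Nat1, Pld1, Ptk2b and Pdk3 passed with slide as a block as well, at log2 differences of 0.89, 1.11, 1.22 and 0.77 and limma adjusted p values of 0.0086, 0.0238, 0.0464 and 0.0395. Without the block their log2 differences were 0.35, 0.29, 0.25 and -0.32. Among the 21 other settings, Pld1 and Ptk2b passed with the fixed block only. Without control replicate 20 Nat1 passed at 0.22 and Pdk3 at -0.60, with limma adjusted p values of 0.0446 and 0.00128. Ptk2b was at -0.044 there. Ldha differed by -0.00067 ± 0.17 (SE), with a limma adjusted p of 0.998. Tnf, Il1b, Il6 and Il10 were not analysed here, because no probe could be named for them.

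Over all probes, 11876 passed the threshold, 5312 higher and 6564 lower in LPS lungs. Of these, 2343 differed at least 2-fold, 1072 higher and 1271 lower. Which direction was the more frequent turned with the scaling: after quantile normalization 6357 were higher and 6066 lower, 1279 and 1123 of them at least 2-fold. In the authors' deposited table, fitted in the same way, 6396 were higher and 6109 lower, 1163 and 1096 of them at least 2-fold. In 5699 called probes the LPS and control values did not overlap, 2299 higher and 3400 lower. Among all tested probes 16.8% showed no overlap, against 0.794% by chance for 5 arrays against 5. Without control replicate 20 the count of called probes with no overlap was 15407, and with slide as a block it was 1613. After normexp background correction 26.8% of them were higher, against 40.3% without it. With slide as a block 3644 probes passed, and 1788 of these had been called in the same direction without it. At least 2-fold with the block were 1592 probes, 918 higher and 674 lower. Without control replicate 20 the counts were 19560 and 3546, without control replicate 17 7886 probes passed, and without control replicate 18 7904. After normexp background correction, which moved the median log2 difference of all probes from -0.05 to -0.21, 18311 probes passed and 19.3% of them were higher, against 44.7% without it.

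The largest rises were at unnamed probes. The largest among those with no overlap rose by 7.30 on the log2 scale, 158-fold, from 0.80 ± 1.84 (SD, n = 5) to 8.10 ± 0.78 (SD, n = 5), with a limma adjusted p of 7.24e-05. On the next probe the rise was 6.11, from -0.93 ± 0.50 (SD, n = 5) to 5.19 ± 0.29 (SD, n = 5), with a limma adjusted p of 6.11e-08. Within slide 3 these rises were 7.32 and 6.53. Of the 18 probes at least 16-fold higher in LPS arrays than in the slide 2 controls, all 18 passed the threshold with slide as a block, and control replicate 20 lay nearer the slide 2 controls on each. Of the 54 probes at least 16-fold lower in LPS arrays, control replicate 20 lay nearer the LPS arrays on 53, and 2 passed with slide as a block. Control replicate 20 was not well above background on 10 of these 54 probes and on 4 of the 18. One of the 54 probes was well above background on all slide 2 controls, on 2 of the 5 LPS arrays and not on control replicate 20. With dim arrays set at their floor, its signal in the slide 2 controls was 361-fold that in the LPS arrays and 624-fold that in control replicate 20.

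**Figure D3:**
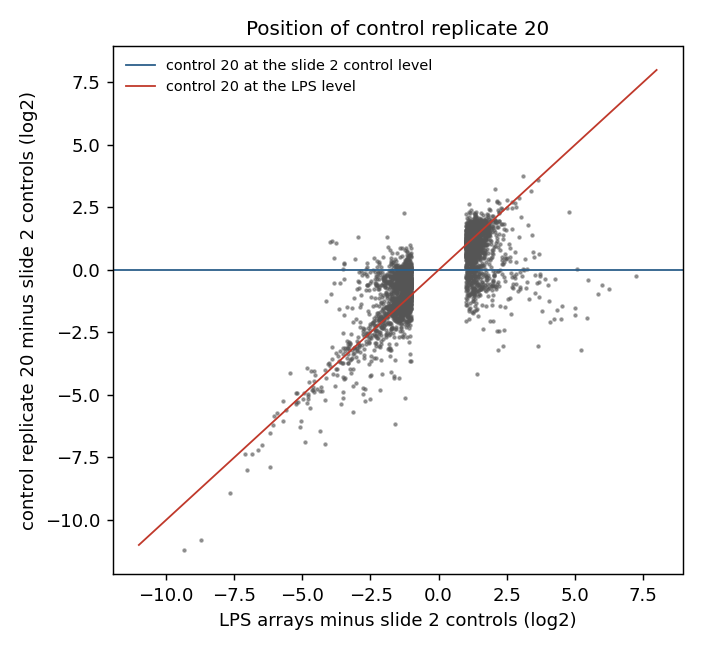
Each point is a probe past the threshold without control replicate 20 and at least 2-fold different between the LPS arrays and the slide 2 controls, with that log2 difference on the horizontal axis and the log2 difference of control replicate 20 from the slide 2 controls on the vertical axis. Control replicate 20 lies nearer the diagonal, the LPS level, on 53 of the 54 probes at least 16-fold lower in LPS arrays, and nearer the horizontal line, the slide 2 control level, on all 18 probes at least 16-fold higher.

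The next comparison asked how long noncoding RNAs differed, transcripts that are not translated into protein. Probes were taken as long noncoding RNA probes from the letters LNC in their identifiers, since the files used here pair no gene name with them. Of 3324 such probes tested, 1083 passed the threshold, 607 higher and 476 lower in LPS lungs, and 187 of them differed at least 2-fold, 117 higher and 70 lower. The 2-fold count was 344 without control replicate 20, and 99 with slide as a block, 39 higher and 60 lower. The probe ASRN6LNC1A100008485V3 rose by 1.96 ± 0.37 (SE) on the log2 scale and ASRN6LNC1A100002736V3 by 1.86 ± 0.15 (SE), with limma adjusted p values of 0.00308 and 1.6e-05. These were not the largest rises of the class. Another such probe was among the 18 at least 16-fold higher in LPS arrays than in the slide 2 controls. The probe ASRN6LNC1A100000649V3 fell by 2.68 on the log2 scale, with SE 0.21, and ASRN6LNC1A100001262V3 fell by 2.40, with SE 0.32. Their limma adjusted p values were 1.09e-05 and 0.000476. ASRN6LNC1A100001262V3 was well above background on 4 of the 5 LPS arrays, so the size of its fall is uncertain. All 4 probes named here stayed past the threshold with slide as a block, at log2 differences of 2.66, 1.37, -2.76 and -1.57. They do not stand for the class: of the 1083 called probes, 114 were called in the same direction with the block.

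The share of long noncoding RNA probes past the threshold was 32.6%, against 33.2% of the other custom probes and 32.9% of those weighted to the same signal levels. The class of the other custom probes is not given in the sources used here, so they may hold long noncoding RNAs too. Long noncoding RNA probes had a median signal of 41.8, against 96.9. Of the called long noncoding RNA probes 56% were higher in LPS lungs, against 43.4% of the other custom probes. With slide as a block 273 were called and 23.4% of these were higher, against 49.7% of the other custom probes, so the order turned. After normexp background correction the shares were 15.3% and 20%, and the order turned as well. Without control replicates 17, 18 and 20 the count of long noncoding RNA probes past the threshold was 699, 696 and 1864.

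Probes named for ultraconserved regions, genome segments identical between human and rodents, were read on both strands. Of 700 tested, 178 passed the threshold, 93 higher and 85 lower in LPS lungs, and 22 of them differed at least 2-fold, or 39 without control replicate 20. They were dim, with a median signal of 23.6. With both strands measured at 268 regions, both probes passed at 20, in the same direction at 12 and in opposite directions at 8. Under independence of the strands 16.6 regions would have both. Across regions the log2 fold changes of the strands had Pearson's r = 0.000827 and Spearman's rho = 0.0147, with regions not being independent replicates. Without LPS replicates 3, 5 and 7 in turn 109, 115 and 109 passed, and without control replicates 16, 17, 18 and 20 in turn 108, 102, 96 and 351. With slide as a block 48 passed, and 10 of these had been called in the same direction without it. The share of calls that were higher was 52.2%, 66.8% after quantile normalization and 5.47% after normexp background correction.

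The last comparison asked whether rats given LPS differed more among themselves than controls. The median SD over probes was 0.19 between LPS arrays and 0.28 between controls, on the log2 scale. The median log2 ratio of the SDs was -0.51, with a 2-sided permutation p of 0.484. For it the 10 group-centred arrays were assigned to sets of 5 in every way. Among the slide 2 controls alone the median SD was 0.17. Without control replicate 20 the log2 ratio was 0.17, with a permutation p of 0.492, so its sign rested on that array.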

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

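The tests on control replicate 20, the slides and the extreme probes were chosen after those values were seen. In 70 sets of 5 arrays, 12 had an array whose gap to its neighbour was large for the range of the set, against about 3.5 by chance, and control replicate 20 was that array in 10. The sets share the same 10 arrays, so 1 array lying apart can mark many of them, and the 12 are not separate events. It was lowest on the first principal component (gap 0.858 of the range) and on the second (0.857). It was also the lowest control for Ndfip2 (0.733), Nat1 (0.767), Pdcd10 (0.763), Enpp1 (0.734), Nlrp3 (0.813), Pdk3 (0.837), Mex3c (0.783) and Trim2 (0.76). The 2 other such arrays were LPS replicate 6, lowest for Napepld in its group (0.718), and LPS replicate 1, highest for Pld1 (0.844).

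Control replicate 20 lay nearer the LPS mean than the slide 2 control mean on 23095 of the 36020 tested probes, 64.1%. It lay nearer the LPS arrays on 1199 of the 1549 probes raised 2- to 4-fold over the slide 2 controls. On probes raised 4- to 8-fold over the slide 2 controls it lay nearer the slide 2 controls on 64 of 108, and on those raised 8- to 16-fold on 23 of 28. Lowered probes went the other way. It lay nearer the LPS arrays on 913 of 1513 lowered 2- to 4-fold, 132 of 200 lowered 4- to 8-fold and 60 of 76 lowered 8- to 16-fold. A mislabelled LPS sample would have the LPS level on probes strongly raised by LPS, but on the 18 probes at least 16-fold higher in LPS arrays than in the slide 2 controls its median position was -0.305 on a scale from the slide 2 controls at 0 to the LPS arrays at 1. That value argues against a mislabelled LPS sample. A difference between slides stays open and cannot be told apart from the samples, since slide 2 held only controls. Between the LPS arrays of slide 1 and slide 3, limma called 1 probe, with 3486 at an unadjusted p under 0.05, which says nothing of slide 2. Those LPS arrays differed at least 2-fold on 1.01% of probes. Control replicate 20 differed at least 2-fold from the mean of the slide 2 controls on 12.6% of probes, a difference among controls alone. The labels set control replicate 20 apart from the other controls in nothing but its number, so no biological explanation was tested.

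The extreme changes went apart. For the 18 probes with the largest rises the position of control replicate 20 was that same -0.305, although it shared its slide with 3 LPS arrays. For the 54 probes at least 16-fold lower in LPS arrays its median position was 1.04, although it was not given LPS. With dim arrays at the lowest signal well above background, these positions were -0.202 and 1.03. Both rest on 1 array, so neither slide for the rises nor LPS for the falls is excluded, and both stay open. At least 8-fold apart between the slide 2 controls and all 6 other arrays were 56 probes. Of these 98.2% were higher in the slide 2 controls, at a median signal of 778 against 25.3 elsewhere. With dim values at the floor 55 were higher and 0 lower. RNA of another tissue or cell type in the slide 2 controls may account for this one-sidedness, as a hypothesis that the probes' missing gene names leave untestable. Among the slide 2 controls their median SD was 0.26, against 0.17 over all probes, and a slide difference or a difference between rats stays open for them.

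Chance as the source of the counts was tested on 100 splits of the 10 arrays into 5 and 5, the real one included. For probes past the threshold 1 split gave as many, the real one with 11876, and the highest other gave 10511. For the 2-fold count it was 1 split, with 2343 against 1424, and for probes with no overlap 1 split, with 5699 against 3914. For long noncoding RNA probes 2 splits gave as many, with 1083 against 1085, and for ultraconserved region probes 2 splits, with 178 against 218. For the first 3 counts only the real split of the 100 gave as many, which is under 0.05. The slides put in doubt that the arrays can be exchanged, so the splits cannot exclude chance. For the long noncoding and ultraconserved counts 2 of 100 splits is also under 0.05, but another split exceeded the real one. The highest other split in all 5 cases set the slide 2 controls and LPS replicate 1 against the rest. It differs from the real split by 1 swap and keeps the slide 2 controls together, so LPS and slide cannot be told apart by it. With slide as a block the long noncoding and ultraconserved counts were 273 and 48.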

How the results depend on the processing

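Slide as a random block, slide 3 alone, and all settings for the no-overlap and ultraconserved counts were chosen after seeing the data. No paired analysis was possible because the groups share no replicate numbers. Not run were the mean over probes of a gene, the gene list and neighbour tests with their alternatives, and variance model, array weights and slide block for the spread, which do not enter it. Probes past the threshold numbered 18311 with normexp, 21921 with array weights, 3644 with slide as a fixed block, 3169 as a random block and 920 on slide 3 alone, where only 1 control informs the test. At least 2-fold they numbered 1088, with the random block 1281 and on slide 3 911. Long noncoding RNA probes numbered 1803, 2060, 273, 211 and 52 in the order of the first count, and 187 at 2-fold. Ultraconserved region probes numbered 402, 402, 48, 18 and 11. Probes with no overlap numbered 1613, 2672 and 920 with the fixed block, the random block and slide 3. Leaving out 1 array at a time gave 7886 to 19560 probes, 1958 to 3546 at 2-fold, 696 to 1864 long noncoding, 96 to 351 ultraconserved and 5223 to 15407 without overlap, highest without control replicate 20 in each. The log2 spread ratio ran from -0.77 to 0.17, positive without control replicate 20 only. For normexp and array weights, whose weight for control replicate 20 was 0.107, the cause was not tested. In 84 other cases these results held within 1.5 times or kept sign and side.

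For the 16 named genes, 258 cases kept sign and side, 43 lost the call, 4 of them with the sign turned (among the 43 Slc28a2, Dlg4, Med16, Map2, Gdnf and Cyp2e1 with the random block, Ndfip2 with trend and robust eBayes and Gdnf in the authors' table) and 15, for Nlrp3, Nat1, Pld1, Ptk2b and Pdk3, gained it, 3 of them with the sign turned. Fgf2 (0.80 to 1.51), Cdh2 (0.76 to 1.11) and Napepld (0.33 to 1.09) stayed past the threshold in all 21 settings. With the fixed block and on slide 3 the sign turned for Dlg4 (0.026 and 0.026), Gdnf (0.15 and 0.15) and Nlrp3 (1.13 and 1.13), though Gdnf and Nlrp3 were not well above background on control replicate 20, and with the random block for Nlrp3 (0.51). Pdk3 turned to 0.77 with the fixed block, 0.77 on slide 3 and 0.29 with the random block. Ptk2b turned to -0.021 with array weights, and ran from -0.044 without control replicate 20 to 0.42 without LPS replicate 1. Ldha, near 0, turned to 0.0302 with normexp, 0.0422 with quantile normalization, 0.0259 with median centring, 0.0366 in the authors' table, 0.50 with the fixed block and on slide 3 and 0.25 with the random block, and ran from -0.11 to 0.066 without 1 array. Dim probes limit what can be called: the median signal after background subtraction was 41.8 for long noncoding and 23.6 for ultraconserved probes. The median local background per array was 16 to 21 before subtraction, and those signals no longer include it.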

Other observations

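The tests of signal level and slide on the direction of long noncoding RNA probes were set before their values were seen, although the pattern itself was known. Called probes with the letters LNC were higher in LPS lungs more often than other called custom probes, whose class is not given, by 12.6 percentage points. Signal level does not account for it, since weighting to equal signal levels left a difference of 14.5 points. With slide as a fixed block the difference was -26.3 points, and with normexp it was -4.77 points, so slide may be the source of the excess, and background correction also stays open. Leaving out 1 array at a time gave 9.47 to 15.8 points. The block rests on control replicate 20 as its only control, so LPS as a cause stays open and untested apart from slide.

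At least 8-fold beyond every control lay the LPS arrays on 11 probes, all higher, and on 0 lower. At least 8-fold higher in the slide 2 controls than in every other array were 55 probes, and 1 was lower. With dim values at the floor the latter counts were 55 and 0. None of the 55 carried the letters LNC or the name of an ultraconserved region.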
